A study of Mus musculus with 16 samples.

How the data were processed

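The data were 2-colour comparative genomic hybridisation arrays of genomic DNA from mouse tails, in which each spot carries a DNA probe and the ratio of the dyes follows the copy number of its sequence in the mouse against the reference. Sample names gave the family member and the dye of each channel. The groups were sire, dam and progeny, with 1, 1 and 6 mice, and the 2 arrays of a mouse with exchanged dyes were counted as 1 replicate of its group. In the limma tests that compare mice with each other, the 2 arrays entered singly, so the spread there is technical.

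Per the file headers, the authors extracted the spot signals with Agilent Feature Extraction 10.7.1.1, and each deposited intensity was background-subtracted, detrended over the array and dye-normalised by a linear factor, with no lowess step. Per the file headers, the log10 ratio that the software gives is Cy5 over Cy3. The authors also deposited a processed table of log2 values. Setting each of its 16 columns against the scanner's log ratio of that array showed log2 of reference over mouse in every column, apart from a constant between -0.012 and 0.011. The column medians lay between -0.005 and 0.009, and the reason for the constant stays unknown. Probe positions were those of the files, on build mm9, and all coordinates are given from 1. How the probes were matched to the genome was not given in the sources used here. The files pair probes with positions and not with genes, and the gene table at hand follows another build, so no genes were named and the comparison with gene family lists was not run.

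Each file held 92168 spots besides control spots. Spots flagged as outliers in either channel, 100 to 146 per array, were left out, no spot was saturated, and 172 to 374 spots per array were not well above background in at least 1 channel. The log2 ratio of the processed Cy5 and Cy3 signals was turned to mouse over reference, spots of a probe were averaged and each array was centred on its median, with no loess or quantile step, since many probes of such an array can truly shift. Among the 56 pairs of arrays with the same dye orientation the correlation over probes lay between 0.162 and 0.732. Over all autosomal probes, with the mean of each dye orientation removed, the 2 arrays of a mouse correlated between -0.273 and 0.42, and in 6 of 8 mice an array of another mouse correlated more closely. The bulk of probes therefore did not check which arrays belong to 1 mouse, and the pairing was taken from the sample names; the X probes and the large regions gave like values on the 2 arrays of each mouse.

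Blocks were formed from probes at most 20 kb apart. In each block the run of probes with the highest absolute sum over noise and the square root of the number of probes was taken from the mean of both dyes, and the flanks were searched again. A call needed a score of at least 6, at least 3 probes, a mean of at least 0.3 in size and at least 0.15 in the same direction in each dye orientation. Calls of different mice in the same direction were merged where they shared at least 50% of the probes of each. A mouse carried a region at 0.3 or more in its direction with at least 0.15 in each dye orientation, lacked it below 0.15 and was unclear between. A region was progeny-only where both labelled parents lacked it, and 7 of the 48 merged regions were left unresolved. Simulated segments were placed in noise made from the dye differences of progeny 1 and progeny 4, with the mean over the mice removed. Of 22 segments of 3 probes at -0.35, 19 were recovered, as were all longer or stronger ones, with 0 false calls over 8209 blocks. The same search on the dye differences of progeny 1 and progeny 4 themselves, with that mean removed, gave 0 and 1 calls, against 11 over all 8 mice. This noise holds no shift shared by both arrays of a DNA, so the 0 false calls do not cover such a shift.

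Windows were 10 consecutive probes of a block, with a last piece of at least 5 kept, and 9957 windows were tested with limma 3.58.1 in R 4.3.3. The model held a term for each of the 8 mice and a dye term over 16 arrays. It was read for equality of the mice, for each progeny mouse minus the mean of the labelled parents (Benjamini-Hochberg over all windows and 6 progeny) and for sire minus the DNA labelled dam. The mean of the 8 mouse values was tested against 0 in a fit of its own. Adjusted p-values are Benjamini-Hochberg values, and the merged regions were tested in the same way over 48 regions. Those regions had been picked on the same arrays, so their tests are not independent of the picking. On simulated windows with the spread of these arrays, 100 changed by 0.4 in 1 progeny mouse among 9957, the test between mice recovered 95 and the test against the parents 99. With a change of 0.2 they recovered 47 and 72 of 100. Over both sizes together, false passes numbered 4 between mice, 10 between progeny and parents, 12 for family against reference and 11 between sire and the DNA labelled dam. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the remaining steps.

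Regions were named in the text by a rule: all progeny-only regions if there were at most 10 and otherwise the 10 with the highest score, the 10 highest-scoring regions of a parent and part of the family, and the 10 highest-scoring regions of all 8 mice. The groups, tests, this rule and most alternatives were fixed before the data were examined. The alternatives were score minimums of 5 and 8, mean minimums of 0.2 and 0.4, at least 5 probes per call, the mean of the dyes without the condition on each orientation, arrays of a single dye orientation, normexp with offset 50, the deposited processed table, centring on the mode, leaving out 522 dim probes, keeping outlier spots, other rules for merging and for carriers, windows of 5 probes, single probes, no dye term, slide as a random block and leaving out single mice. The files used here hold median but no mean spot signals, so normexp was run on the median spot and background signals. Calls of at least 10 probes, calls without the DNA labelled dam, the test of progeny against the sire alone, windows outside the merged regions and the dye difference with its mean removed were chosen after seeing the data.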

Results

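DNA copy number was compared along selected parts of the genome in 1 family of C57BL/6JNrs mice. The family held a sire, a dam and 6 progeny, and the DNA came from tails taken after death. The series title describes male mice kept under gamma-rays at 1 mGy per day for 400 days. Its design text instead calls the parents of the 1 mGy family not irradiated, and names that family 1mGyD where the samples are 1mGyA. The exposure of the sire is therefore not settled by the labels. No family of unexposed mice is part of the comparisons here, and an effect of radiation cannot be read from them. Each DNA was hybridised on 2 arrays against 1 male reference mouse of the same colony, with the dyes Cy3 and Cy5 exchanged, which gave 16 arrays. The array was designed by the study around probes that had stood out in its earlier screen of the family, so its regions are not independent evidence, and 88104 distinct probes were placed on mouse genome build mm9. A block of at least 5 neighbouring probes was present at 4672 places, with a median of 16 probes per block. The median signal per array lay between 896 and 1485 in Cy5 and between 496 and 876 in Cy3, and the signal-to-noise ratio reported by the scanner software lay between 112 and 181. All values below are log2 ratios of mouse over reference, the opposite of the deposited processed table, and an SD over 2 arrays is that of the exchanged dyes of 1 DNA, so it is technical. The number of mice, 1 per parent and 6 progeny, limits the precision.

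The X and Y probes, used as a check of the labels, gave a raised X signal and a lost Y signal in progeny 2, 5 and 6. The mean over 48 X probes was 0.89 ± 0.08 in progeny 2, 0.91 ± 0.08 in progeny 5 and 0.94 ± 0.10 in progeny 6 (SD, n = 2 arrays). The 3 Y probes gave -5.07, -2.89 and -0.38 in progeny 2, and the same probes gave -4.91, -2.96 and -0.51 in progeny 5 and -4.79, -3.10 and -0.46 in progeny 6. In the sire, the DNA labelled dam and progeny 1, 3 and 4 the X mean lay between -0.03 and 0.00 and the Y mean between -0.06 and 0.04, so these DNAs gave the ratio of a male against the male reference. The DNA labelled dam thereby went against its label, and every statement about a parent below carries that limit.

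**Figure D1:**
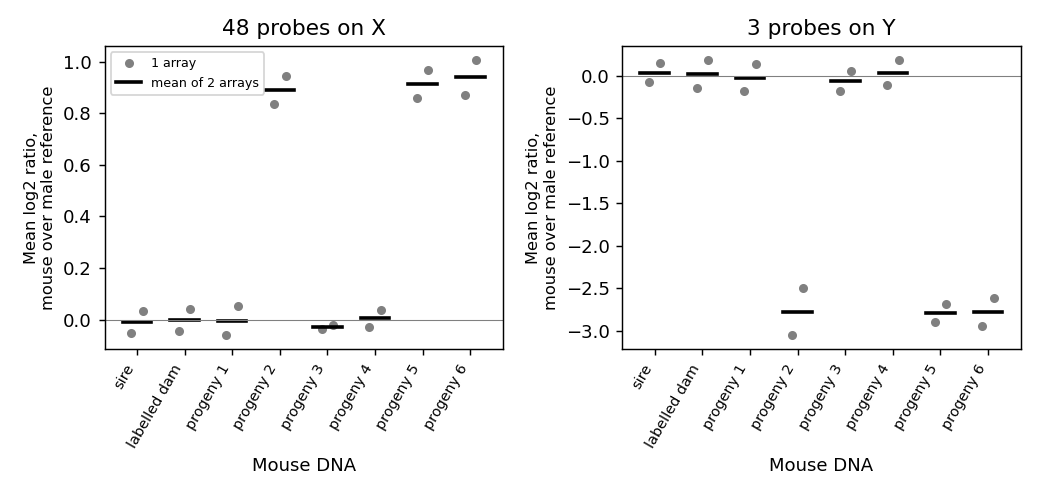
Mean log2 ratio of mouse over male reference for 48 probes on X (left) and 3 probes on Y (right) in each of the 8 mouse DNAs, with grey points for single arrays and black bars for the mean of 2 arrays. Progeny 2, 5 and 6 lie between 0.89 and 0.94 on X, and the DNA labelled dam lies at 0.00.

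The region with the most probes was a gain on chromosome 4. Over 1039 probes from 101110482 to 101270967, a length of 160486 bp, the sire had the level of the reference at 0.00 ± 0.03 (SD, n = 2 arrays). The DNA labelled dam was at 0.48 ± 0.03, and progeny 1, 3, 4, 5 and 6 lay between 0.47 and 0.49. Progeny 2 was higher than all of them at 0.80 ± 0.05. The difference between sire and the DNA labelled dam was -0.48 ± 0.03 (SE, limma adjusted p = 3.5e-06), and progeny 2 exceeded the mean of the labelled parents by 0.56 ± 0.03 (SE, limma adjusted p = 4.01e-07). The other 5 progeny had the level of the DNA labelled dam, and their distance of 0.23 to 0.25 from that mean follows from the sire's level of 0.00, which the mean includes. The first probe of the tiled block was already raised, and the nearest probe to its left, at 100957022, lay between -0.06 and 0.11 in the 8 mice, so the left end falls in the untiled stretch between them. On the right, the 10 probes from 101270969 to 101271749 averaged between -0.02 and 0.01 in all 8 mice.

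**Figure D2:**
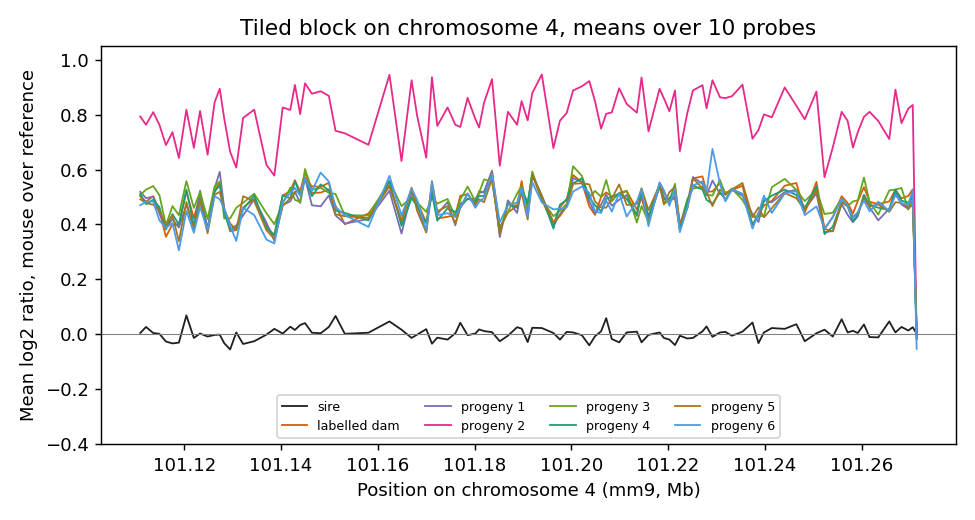
Mean log2 ratio of mouse over reference over 10 consecutive probes along the tiled block on chromosome 4 (mm9, Mb), with 1 line per mouse DNA as the mean of 2 arrays. The sire runs at 0, the DNA labelled dam and 5 progeny at 0.47 to 0.49 and progeny 2 at 0.80, and all lines return to 0 at the right end.

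The design asked which regions passed from parents to progeny. Of 48 merged regions, 7 were carried by a labelled parent and not by the whole family: 1 by the sire and not the DNA labelled dam, 5 by the DNA labelled dam and not the sire, and 1 by both. Progeny carriers were found for 3 of the 7, the chromosome 4 gain and the losses on chromosomes 1 and 4, and the other 4 had none over the whole region. Within 2 of these 4, both on chromosome 14, a shorter run was called in a progeny mouse, at -0.355 over 8 probes from 54389667 to 54390579 in progeny 2 and at -0.305 over 21 probes from 54279176 to 54297307 in progeny 6. Regions of opposite direction were kept apart, and 5 places were called in both directions, so the 48 regions lie at 43 places. The region of both was a loss on chromosome 1 from 21797113 to 21797777, 7 probes over 665 bp, at -1.01 ± 0.11 in the sire and -0.95 ± 0.08 in the DNA labelled dam (SD, n = 2 arrays). Progeny 3, 5 and 6 carried it at -1.04 to -0.96, and progeny 1, 2 and 4 lay between -0.04 and -0.01. The region of the sire was a loss on chromosome 4 from 78496780 to 78509788, which spans a whole block of 16 probes, at -0.34 ± 0.05 in the sire and -0.35 ± 0.06 in progeny 3. The remaining mice, the DNA labelled dam among them, lay between -0.01 and 0.04 there, and sire minus the DNA labelled dam was -0.35 ± 0.03 (SE, limma adjusted p = 3.64e-05). The level of the carriers of this loss was smaller in size than the -1.04 to -0.95 in carriers of the chromosome 1 loss. Its copy number was not settled. The 5 regions of the DNA labelled dam were the chromosome 4 gain, 3 regions on chromosome 14 and a run of 3 probes on chromosome 15. On chromosome 14 that DNA passed the minimum of 0.3 for a carrier with -0.31 to -0.32 while the other 7 mice lay between -0.22 and -0.29, and sire minus the DNA labelled dam passed no threshold (limma adjusted p = 0.139, 0.246 and 0.139). On chromosome 15, from 14019427 to 14019606, the level of -0.33 in the DNA labelled dam went to -0.01 without probes close to the background. Without the DNA labelled dam, an alternative chosen after seeing the data, 2 regions were carried by the sire and part of the family.

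**Figure D3:**
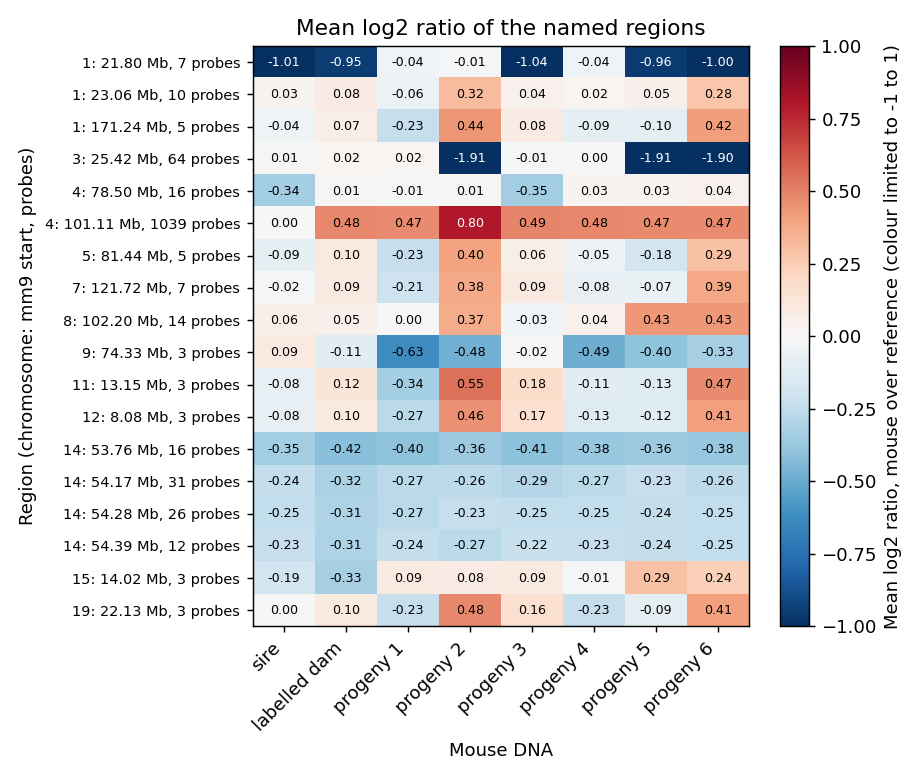
Mean log2 ratio of mouse over reference in the 18 named regions (vertical axis, chromosome with mm9 start and number of probes) in the 8 mouse DNAs (horizontal axis), with colour limited to the range from -1 to 1. The chromosome 4 gain that starts at 101110482 is absent from the sire, at 0.00, and the chromosome 3 loss that starts at 25417435 is carried by progeny 2, 5 and 6 at -1.91, -1.91 and -1.90.

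A single region was carried by all 8 mice, so that family and reference differed there. It lay on chromosome 14 from 53759005 to 53763191, 16 probes, at -0.42 to -0.35, with a mean of -0.38 over the 8 mice (limma adjusted p = 6.62e-06 against 0, lower in 8 of 8 mice). The region was picked because all 8 mice passed the minimum on these arrays, so this direction and test are not independent of the picking. At this place the difference can lie in the reference mouse, whose own spread is not in the test, and the 8 mice are relatives. A mean of -0.15 or lower in all 8 mice was found in 6 of 4672 blocks, all on chromosome 14 between 53759005 and 54391070, a span of 632066 bp. The mean over the 8 mice in these 6 blocks, 179 probes in all, lay between -0.38 and -0.22. A block of 16 probes from 54073238 to 54075100 inside that span lay between -0.06 and 0.05. No block was at 0.15 or higher in all 8 mice.

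Regions carried by progeny and by neither labelled parent were the question of the series, and 33 were found, 24 higher and 9 lower than the reference. They lie at 31 places, since 2 places counted once as higher and once as lower in different progeny. Of these, 29 had under 10 probes and 26 had 3 or 4. The clearest was a loss on chromosome 3 from 25417435 to 25448261, 64 probes over 30827 bp, at -1.91 ± 0.05 in progeny 2, -1.91 ± 0.04 in progeny 5 and -1.90 ± 0.03 in progeny 6 (SD, n = 2 arrays), with the other 5 mice between -0.01 and 0.02. A gain on chromosome 8 from 102200691 to 102202365, 14 probes, was carried by the same mice at 0.37, 0.43 and 0.43, with the other 5 between -0.03 and 0.06. These 3 mice are the ones with the raised X signal. The mean of the labelled parents was exceeded by 0.32 ± 0.05, 0.37 ± 0.05 and 0.37 ± 0.05 on chromosome 8 (SE, limma adjusted p = 0.000705, 0.00024 and 0.00024), and the deficit on chromosome 3 had an adjusted p of 8.38e-11 in each of the 3. A loss over 3 probes on chromosome 9, from 74330099 to 74330215, was carried by 5 of the 6 progeny. Its level was -0.63 ± 0.19 in progeny 1, -0.48 ± 0.16 in progeny 2, -0.49 ± 0.07 in progeny 4, -0.40 ± 0.24 in progeny 5 and -0.33 ± 0.19 in progeny 6, against -0.02 in progeny 3, 0.09 in the sire and -0.11 in the DNA labelled dam. The difference from the labelled parents passed the test in each of the 5 (limma adjusted p between 0.00115 and 0.0327). The regions on chromosomes 3, 8 and 9 were picked on the same arrays, so these tests are not independent of the picking.

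The other 7 progeny-only regions with the highest scores were short, carried by progeny 2 in all 7 and by progeny 6 in 5, all of them gains. On chromosome 1 they lay from 23057475 to 23058301 (10 probes) and from 171244584 to 171244935 (5 probes), with 0.32 and 0.44 in progeny 2 and 0.28 and 0.42 in progeny 6. On chromosome 5 the region from 81444285 to 81444678 (5 probes) was at 0.40 in progeny 2 and 0.29 in progeny 6, and on chromosome 7 the region from 121722276 to 121722741 (7 probes) was at 0.38 and 0.39. Progeny 6 lay under the minimum of 0.3 in the first region of chromosome 1 and in that of chromosome 5, and its difference from the labelled parents in the former did not pass (limma adjusted p = 0.0868, against 0.0462 in progeny 2). Runs of 3 probes on chromosome 11 from 13154197 to 13154299, on chromosome 12 from 8080191 to 8080590 and on chromosome 19 from 22128005 to 22128538 were at 0.55, 0.46 and 0.48 in progeny 2 and 0.47, 0.41 and 0.41 in progeny 6. Progeny 1 lay below the reference in all 7, between -0.34 and -0.06, and its -0.34 on chromosome 11 was itself counted as a lower region of the same probes. Of the 22 higher regions with under 10 probes, 22 were carried by progeny 2 or 6, and progeny 1 was below 0 in 17. In the limma test of each progeny mouse against the mean of the labelled parents, 30 of the 33 regions passed in at least 1 progeny mouse, but the regions had been picked on the same arrays. With at least 5 probes per call 7 such regions were left, and with at least 10 probes, a minimum chosen after seeing the data, 4 were left.

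Per mouse, 3 regions were called in the sire and 7 in the DNA labelled dam. Among the progeny, 8 were called in progeny 1, 30 in progeny 2, 6 in progeny 3, 3 in progeny 4, 7 in progeny 5 and 25 in progeny 6. Of the 89 calls, 51 were higher and 38 lower than the reference, 47 had 3 or 4 probes and 29 had at least 10. The same search on the difference between the dye orientations, which carries no copy number signal, gave 206 calls, 2 of them with at least 10 probes. That difference had a probe-to-probe noise of 0.082 to 0.104 against 0.046 to 0.064 for the mean of the dyes. After removal of the mean dye difference of the 8 mice, a step added after seeing the data, 11 calls remained, none with at least 10 probes. A shift shared by both arrays of a DNA cancels in that difference, so these calls do not cover it.

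Windows of 10 neighbouring probes, fixed by position alone, gave a comparison that did not depend on the calls. Differences between mice passed in 146 of 9957 windows (limma F-test, adjusted p under 0.05), of which 104 belonged to the 105 windows of the chromosome 4 block. Sire and the DNA labelled dam differed in 107 windows, 104 of them in that block, with 1 higher and 106 lower in the sire. Against the mean of the labelled parents, 106 windows passed in progeny 1, 137 in progeny 2, 105 in progeny 3, 102 in progeny 4, 124 in progeny 5 and 138 in progeny 6. Outside the chromosome 4 block these were 11, 33, 2, 3, 28 and 42 windows. Progeny 2, 5 and 6, with 33, 28 and 42, are the mice with the raised X signal. Both labelled parents gave male ratios, so a difference from them that these mice share and the other progeny lack cannot be told apart from one of sex. Not every window is of that kind. On chromosome 1 from 171244584 to 171244935, progeny 2 and 6 lay at 0.44 and 0.42 and progeny 5 at -0.10. In that block 95 to 103 windows passed in each progeny mouse other than progeny 2, whose levels there were those of the DNA labelled dam, because the mean of the labelled parents lies between the parents. The spread in these tests is that between 2 arrays of 1 DNA, and each pair of mice shared a slide scanned on a day of its own, so that parents and progeny cannot be told apart from slide and day. Within the slide of the parents alone, sire and the DNA labelled dam differed in 196 windows.

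The mean of the 8 mice differed from the reference in 1488 of 9957 windows (limma, adjusted p under 0.05), 635 higher and 853 lower, with a median size of 0.04. A size of at least 0.3 was reached in 109 of them: 104 on chromosome 4 in the gain, 4 on chromosome 14 and 1 at the chromosome 1 loss. Centring on the mode in place of the median turned the split to 658 higher and 503 lower. The total fell to 596 without the DNA labelled dam, 754 without progeny 6, 779 without the sire, 817 without progeny 5, 877 without progeny 3 and 916 without progeny 4. It rose to 1639 without progeny 1 and to 1870 without progeny 2.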

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

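The tests of explanations in this part were all chosen after the results were seen, and the outlier test was fixed beforehand. Of 19 values tested over the 6 progeny, 2 had a progeny mouse far from the other 5, where chance gives about 1 in 20 among values not picked beforehand. That rate does not hold here, since 18 of the 19 were levels of regions named because a mouse departed from the reference. Progeny 3 stood apart over the loss on chromosome 4 that starts at 78496780, at -0.35 against -0.01 to 0.04 in the other 5, and it shares that level with the sire at -0.34.

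Progeny 2 stood apart over the chromosome 4 gain, at 0.80 against 0.47 to 0.49 in the other 5 progeny, while the sire was at 0.00 and the DNA labelled dam at 0.48. This goes together with the male X and Y ratios of the DNA labelled dam and with the chromosome 9 loss in 5 progeny and neither labelled parent. Correct labels and a change that arose in progeny 2 are argued against by the X mean of -0.003 in the DNA labelled dam. A candidate explanation is an exchange of the DNA labelled dam with that of progeny 2, but a check of transmission from sire and dam could not decide it: of 6 regions, 2 follow the X signal and 2, the chromosome 4 gain and the chromosome 9 loss, prompted the explanation, and the remaining 2 gave 0 conflicts whichever of the 7 DNAs besides the sire was taken as the dam. A single wrong label on the DNA called dam, with all progeny labelled correctly, stays open too, since the excess of 0.31 of progeny 2 over the highest other progeny may come from a dam not on these arrays with different copy numbers on its chromosomes, and the sire's exposure was not tested.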

How the results depend on the processing

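Of 160 recomputed counts, 112 stayed within 1.5 times the reported one. Among them were all under score minimums of 5 and 8, the deposited processed table, mode centring, outlier spots kept and dim probes left out. The score minimums could not change a count, since a run that meets the other conditions of a call already scores above 8 at this noise. Centring removes the constant of the deposited table, so that table was no independent check. For the 48 counts beyond 1.5 times the cause was not tested, except where fewer probes, mice or windows follow from the alternative itself. In the order calls, merged regions, regions of all 8 mice, of a parent and part of the family and of progeny alone (reported 89, 48, 1, 7 and 33), a minimum mean of 0.2 gave 227, 130, 7, 15 and 75 and one of 0.4 gave 40, 18, 0, 3 and 12. At least 5 probes gave 42 calls, 15 regions and 7 of progeny alone, and at least 10 probes, added after seeing the data, gave 29, 10 and 4. Arrays with the mouse in Cy5 alone gave 398 calls, 229 regions, 3 of all 8 mice and 98 of a parent, and those with the mouse in Cy3 gave 384, 241, 2 and 58 with 74 of progeny alone. Leaving out a progeny mouse or, added later, the DNA labelled dam gave 1 to 2 regions carried by all remaining mice and 2 to 7 of a parent, both at 2 without that DNA. For windows between mice, between progeny and parents, between family and reference and between sire and the DNA labelled dam (reported 146, 712, 1488 and 107), single probes gave 1082, 2020, 5789 and 789. Windows of 5 probes gave 281 between mice, 1255 between progeny and parents and 214 between sire and the DNA labelled dam. A size of at least 0.3 left 149 for progeny against parents and 109 for family against reference. Without a dye term 97 windows differed between mice and 292 between progeny and parents, and the parents' slide alone gave 196. Leaving out a mouse gave 596 to 1870 windows for family against reference, with 596 without the DNA labelled dam and 1870 without progeny 2. The counts were 754, 779, 817, 877 and 916 without progeny 6, the sire and progeny 5, 3 and 4. Outside the merged regions, counted after seeing the data, 18 windows differed between mice and 63 between progeny and parents. Between sire and the DNA labelled dam 0 differed in limma. Of 9752 such windows 122 had an unadjusted p under 0.05 there, fewer than chance alone gives. Against the sire alone, added later, 721 windows passed for the progeny. Slide as a random block could not act on the test between mice, whose terms already hold the slide. Levels of the 18 named regions were recomputed 126 times, and 4 moved beyond the spread of 2 arrays with 0 changes of sign. Levels from a single dye orientation could not pass that spread, which comes from the same 2 arrays. Their sign was fixed by the rule for carriers. Levels from the deposited table had little room to move, since centring removes its constant. The comparison with gene family lists and its alternatives were not run. No paired analysis was possible, because the sire and dam groups hold 1 mouse each and the replicate numbers of the samples define no pairs.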

Other observations

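The tests of explanations in this part were all chosen after the results were seen. A single probe on chromosome 13, at 95707465 to 95707524, lay between 1.85 and 2.02 in all 8 mice, the only autosomal probe outside the merged regions with a size of at least 1 on each of the 16 arrays. It was too short for a call. A loss on chromosome 5 from 121062932 to 121063660, 10 probes, was carried by progeny 6 alone at -0.32 ± 0.19 (SD, n = 2 arrays), with -0.15 in progeny 2 and -0.14 in progeny 5, and was picked for mention after its values were seen. Its difference from the labelled parents was -0.33 ± 0.08 in progeny 6 (SE, limma adjusted p = 0.00781).

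The loss on chromosome 3 and the gain on chromosome 8 appeared in progeny 2, 5 and 6, the mice with the raised X signal. A loss of 1 autosomal copy on chromosome 3 is argued against by the mean level of -1.91 in the 3 carriers, which is below the -1.04 to -0.95 of the chromosome 1 loss. Probe sequence shared with the Y chromosome on chromosome 3 and with the X chromosome on chromosome 8 may account for both, but that all 16 states of 8 mice at 2 regions matched the X signal is how the pattern was noticed and decides nothing. Probe sequence was not compared with the genome here, so this account stays open. Inheritance of a loss of both autosomal copies on chromosome 3 is argued against by the sire's level of 0.01 ± 0.09 (SD, n = 2 arrays). The sire would have had to pass on a loss to each carrier. A loss of both copies that was not inherited stays open. Inheritance of an autosomal gain on chromosome 8 stays open too, with the sire at 0.06, since the labels do not settle the dam.

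Of the 29 short regions of progeny alone, which lie at 27 places, 24 were carried by progeny 2 or 6 and 11 by both. A graded difference between DNA preparations or hybridisations that runs over the whole array may account for part of them: in 9752 windows of blocks without a merged region, the projection on the profile of the 29 regions over the mice correlated at 0.386 between the Cy5 and the Cy3 arrays, a value reached by 13 of 1000 random profiles. This correlation is across windows, which are not independent replicates. New changes of 1 copy in progeny 2 and 6 as the whole cause of the short gains stay open: with places called in both directions left out, another mouse lay at -0.15 or lower in each dye orientation in 9 of 19 short gains (47.4%), against at most 3 of 19 in 1000 random sets of runs of as many probes elsewhere, but places picked by a search can hold noisier probes. What sets the gradient was not tested.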
